A study of Arabidopsis thaliana with 9 samples.

How the data were processed

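RNA from freshly harvested Arabidopsis thaliana seeds was sequenced in 9 libraries, 3 in each of 3 groups. The groups were DOF6ioex seeds in mock solution, DOF6ioex seeds in estradiol and rgl2-13 DOF6ioex seeds in estradiol, all imbibed for 8 h and, where treated, at 50 µM. DOF6ioex is a line in which estradiol induces overexpression of the transcription factor gene DOF6, and rgl2-13 is a mutant allele of RGL2, a DELLA gene of gibberellin signalling.

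Reads were aligned with HISAT, per the submitters' processing notes. The version, the genome build and the tool that quantified genes are not given in the sources used here. The deposited tables give FPKM per gene, per the file headers, with 2 decimals and a lowest value of 0.01. In 1 of the 6 pairwise tables both value columns are headed RPKM, per the file headers; the values of the library it shares with another table, which is headed FPKM, were identical there, so all were treated as 1 unit. Each table sets 1 library against another of the same replicate number and adds a log2 ratio of the pair, per the file headers, which equalled the log2 of the 2 printed values. The authors also gave a p-value for each pair of libraries, from a test that is not named, and an FDR column. In 2 tables the deposited FDR column runs just above 1 and was therefore read as a score. A further 2 deposited tables list the genes past the authors' own threshold, pair by pair. These pairwise tests were not used for the results here.

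The tables were joined into 22555 genes by 9 libraries, with a gene missing from a library's table set to 0.01. Of 22415 gene loci, 22230 matched the TAIR10.1 gene table, which was used for symbols and gene order alone, because the files name no build. The other 140 genes carry names given by the authors' pipeline. Counts had been planned for, with a count-based test. As the files hold FPKM, the test written down beforehand for that case was used: limma 3.58.1 in R 4.3.3, with the mean-variance trend, on log2(FPKM + 1). Genes at 1 FPKM or more in at least 3 libraries were kept, which left 13679. All 9 libraries entered 1 model with a mean per group and no covariate, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of genes with low values. No further scaling was applied.

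FPKM hides the depth, but low values lay near whole multiples of what 1 fragment is worth. Within 0.15 of a whole number, 78.2% to 85.7% of the low values were whole with full gene lengths, and 85.0% to 92.1% with 50 bases taken off, where chance gives 30%. From these steps the depth was estimated at 26900000 to 29300000 fragments per library with full lengths, with libraries differing by at most 1.09 times. With 50 bases taken off, where more values were whole, it was 29200000 to 31300000, differing by at most 1.07 times. This is an estimate, and no counting interval was derived from it.

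The 3 comparisons were estradiol against mock in DOF6ioex, the libraries labelled rgl2-13 DOF6ioex against DOF6ioex in estradiol, and the libraries labelled rgl2-13 DOF6ioex in estradiol against DOF6ioex mock. The last differs in both genotype and treatment. A total of 26 gene lists was fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The fry test was planned beside it. It asks whether list members change, not whether they change more than other genes, and its p are unadjusted. In the ribosomal list 1 protein entry, contradicted by its reference symbol, was dropped after its values had been seen. Genes named in the text follow a rule also fixed beforehand. It takes DOF6, RGL2 and GATA12, and up to 12 of the largest rises and 12 of the largest falls per comparison, among called genes whose groups do not overlap and whose higher group averages at least 5 FPKM. It adds up to 4 called members per list, or 2 where none passed, and genes called in opposite directions in both main comparisons. A gene outside the rule is marked as such where it appears.

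The fit was tested on simulated data, 20 datasets with 200 changed genes among 13679. For estradiol against mock it called 59.0% of genes changed by log2 0.50, 98.4% at 1.00 and 99.9% at 2.00, with 5.69% of calls false. For the genotype comparison it called 55.6%, 99.2% and 99.9%, with 5.17% false. Lists were simulated for estradiol against mock alone and scored at an unadjusted camera p under 0.05. The same settings called 100% of 50 simulated lists of 15 genes shifted by log2 0.50 and 0% of unshifted ones. The simulated genes varied independently of each other. This test therefore cannot show how often the preset correlation calls lists of correlated genes falsely.

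Alternatives were another pseudocount, no filter on low values, median-of-ratios and upper quartile scaling, a fit on 6 libraries, the replicate number as a block, 2 stricter thresholds on fold change, and each library left out in turn. Library weights, the GO terms of the deposited annotation and 2 further gene lists were added after seeing the data. Figures were drawn with matplotlib in Python.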

Results

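The data are FPKM values of 13679 expressed genes in 9 seed libraries, 3 per group. The depth was estimated at 26900000 to 29300000 fragments each with full gene lengths and 29200000 to 31300000 with 50 bases taken off. EPR1, an endosperm gene for an extensin-like protein, had the highest value in each of the 9 libraries. Seed storage and oil body transcripts made up 14.7% to 21.5% of the FPKM total, and mitochondrial transcripts 0.0425% to 0.103%. In a principal component analysis of all tested genes, the first component (45.6% of the variance) set replicate 1 of the libraries labelled rgl2-13 DOF6ioex at 37.3, with the other 8 libraries between -12.9 and 7.1. The second component (18.5%) set mock replicates 1 and 2 at 14 and 17.3 and mock replicate 3 at -1.

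DOF6 (AT3G45610) averaged 0.637 ± 0.225 FPKM (SD, n = 3) in mock seeds and 33.9 ± 1.98 (n = 3) in DOF6ioex seeds in estradiol. The libraries labelled rgl2-13 DOF6ioex held 33.7 ± 16.3 FPKM of DOF6 (n = 3), from 21.4 in replicate 2 to 52.2 in replicate 1. RGL2 (AT3G03450), the gene that the rgl2-13 allele affects, averaged 10.8 ± 2.13 FPKM in mock, and 8.59 ± 1.39 in DOF6ioex estradiol (each n = 3), and the 3 libraries labelled rgl2-13 DOF6ioex held 17.9, 16.1 and 18.8 FPKM. RGL2 was thus higher, not lower, in the libraries that carry the mutant label. GATA12 (AT5G25830), a GATA factor gene linked to dormancy, was at or near the lowest listed value of 0.01 FPKM in the 9 libraries, with a highest value of 0.04, so that no change in it was detectable at this depth.

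**Figure D1:**
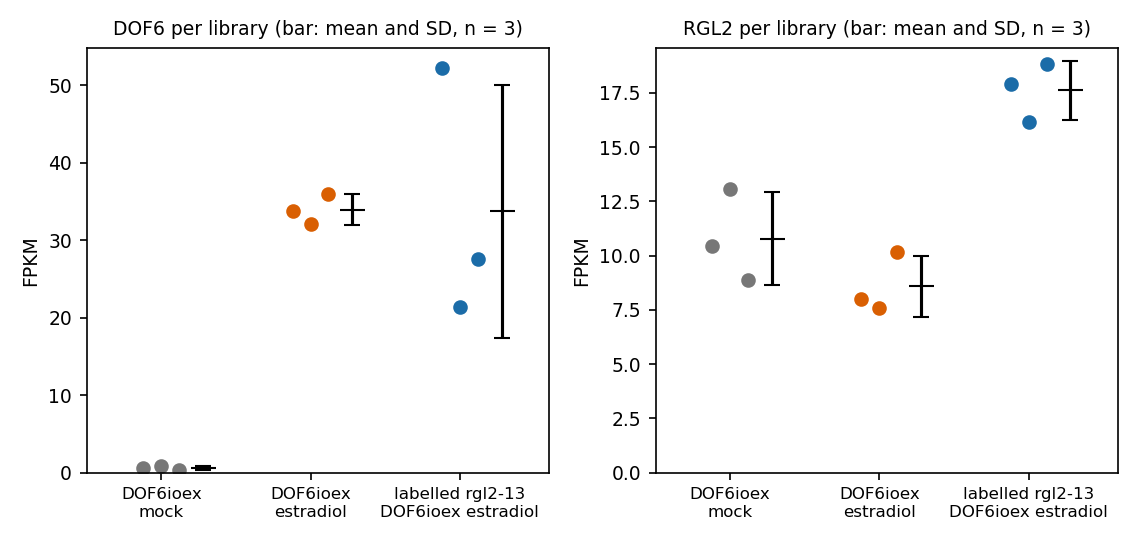
FPKM of DOF6 and RGL2 in each of the 9 libraries by group (points), with the mean and SD of each group (n = 3) beside them. DOF6 was near 0 in mock and averaged 33.9 and 33.7 FPKM in the estradiol groups, and RGL2 was highest in the 3 libraries labelled rgl2-13 DOF6ioex, between 16.1 and 18.8 FPKM.

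The comparison of estradiol with mock in DOF6ioex seeds asks which transcripts change when DOF6 is induced. No line without the construct was treated. For every gene and list below, an effect of estradiol itself therefore cannot be told apart from one of DOF6. Besides DOF6, which rose by log2 4.42 ± 0.24 (SE; adjusted p = 7.39e-06), DIN2, a beta-glucosidase gene, rose from 14.1 ± 3.62 to 38.0 ± 5.59 FPKM. LSU3, a gene of the response to low sulfur, rose from 4.60 ± 0.437 to 9.52 ± 0.685 FPKM. Larger in number were the falls. FTM1, for a stearoyl-ACP desaturase, fell by log2 1.56 ± 0.13 (adjusted p = 0.000314), from 5.50 ± 0.669 to 1.22 ± 0.352 FPKM. PDC1, for pyruvate decarboxylase of ethanol fermentation, fell by log2 1.17 ± 0.16 (adjusted p = 0.0165), from 94.9 ± 3.14 to 42.1 ± 7.35 FPKM (n = 3 for each mean ± SD).

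In all, 21 genes changed in limma at an adjusted p under 0.05, 4 up and 17 down. Of them 14 changed at least 2-fold on the log2(FPKM + 1) scale, which counts fewer than plain FPKM would. The groups did not overlap for any of the 21, while 14.9% of all genes were separated in this way and chance gives 10%. A gene called with 3 libraries per group is nearly bound to be separated, so this is no further support for the calls. The transcription factor gene HRA1 fell by log2 1.07 ± 0.17, from 65.6 ± 4.99 to 30.7 ± 2.59 FPKM. NRT2.6, of the nitrate transporter family, fell by log2 1.01 ± 0.13, from 5.54 ± 0.641 to 2.24 ± 0.231 FPKM. AT4G10270, of a wound-responsive family, fell by log2 1.33 ± 0.20, AT2G17850, of a rhodanese family, by -1.21 ± 0.15, and AT1G12805, annotated as a nucleotide binding protein, by -1.20 ± 0.18. The uncharacterised genes AT1G33055, AT3G23170 and AT5G65207 changed by log2 -1.22 ± 0.15, -0.90 ± 0.15 and -0.75 ± 0.10. AT4G17940, for a tetratricopeptide repeat protein, changed by log2 -0.61 ± 0.10. The adjusted p of these genes lay between 0.00595 and 0.0408. BGLU28, below the level set for naming and listed here after its values were seen, rose from 0.0700 ± 0.0529 FPKM in mock to 1.54 ± 0.505 in estradiol. On the log2(FPKM + 1) scale, which understates changes at such low values, this was 1.23 ± 0.20.

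**Figure D2:**
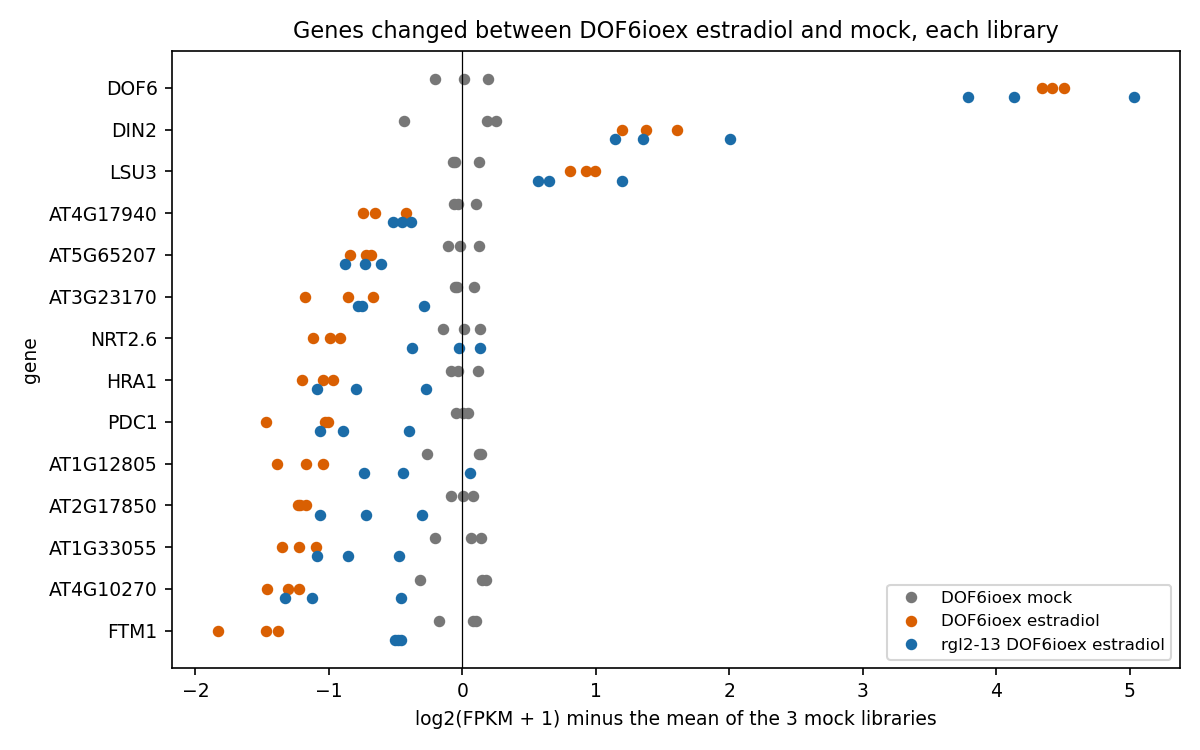
Each point is 1 library, as log2(FPKM + 1) minus the mean of the 3 mock libraries, for the genes that changed between DOF6ioex estradiol and mock and met the naming rule. Estradiol libraries of both genotype labels lie on the same side of the mock mean for most genes. On average most of the genes that fell lie nearer to mock in the libraries labelled rgl2-13 DOF6ioex than in DOF6ioex estradiol. The genes were chosen for their difference between DOF6ioex estradiol and mock, so this position may come partly from the choice. Of the genes shown, FTM1 and NRT2.6 were called for that difference.

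Among the fixed gene lists, those of xenobiotic response and heat shock stood higher in estradiol than other genes, and cell wall loosening stood lower. In camera each passed only with the preset correlation (adjusted p = 0.535 with an estimated correlation for each). The unadjusted fry p of these lists were 0.0494, 0.0521 and 0.0713. Of 15 measured xenobiotic response genes 14 were fitted higher (median log2 0.20; camera adjusted p = 0.000763; adjusted p = 0.535 with an estimated correlation), and none passed alone, while 2 did adjusted over the list alone. UGT74E2 and OPR1 had values of 140 ± 14.0 and 14.8 ± 1.46 FPKM in mock and 229 ± 27.3 and 21.1 ± 2.79 in estradiol. Of 15 heat shock genes 14 were fitted higher (median log2 0.20; adjusted p = 0.00111; adjusted p = 0.535 with an estimated correlation), with HSP101 at 181 ± 25.7 FPKM in mock and 233 ± 11.3 in estradiol, and none passed alone or adjusted over the list alone. Of 13 cell wall loosening genes 10 were fitted lower (median log2 -0.23; adjusted p = 0.00111; adjusted p = 0.535 with an estimated correlation), none passed alone, and 2 did adjusted over the list alone. The expansin genes EXPA10 and EXPA1 held 8.02 ± 1.06 and 10.8 ± 2.09 FPKM in mock, against 4.23 ± 0.562 and 6.30 ± 1.05 in estradiol. Leaving out mock replicate 2 brought the xenobiotic median to 0.13 and the cell wall median to -0.11, and leaving out DOF6ioex estradiol replicate 1 brought the latter to -0.14, with the calls past the threshold; without the filter it was -0.09.

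A further 6 lists passed, and each of these calls was lost without 1 or more single libraries and with an estimated correlation. Seed storage and oil body genes were lower by a median log2 of -0.10 (15 of 16 fitted lower; adjusted p = 0.0036; adjusted p = 0.569 with an estimated correlation), a shift that rests on mock replicate 1: without it the median was 0.01 (adjusted p = 0.644), and without DOF6ioex estradiol replicate 3 the adjusted p was 0.101. Cytosolic ribosomal protein genes were lower by -0.09 (18 of 22, adjusted p = 0.0261, and 0.866 with an estimated correlation). They were not past the threshold without mock replicate 1 or 2 or DOF6ioex estradiol replicate 1 (adjusted p = 0.0946, 0.47 and 0.169). Their median was then -0.05, -0.05 and -0.02. Gibberellin signalling was lower by a median log2 of -0.11 (adjusted p = 0.0261; adjusted p = 0.602 with an estimated correlation), but at 0.02 without DOF6ioex estradiol replicate 2 (adjusted p = 0.207) and lost without mock replicate 2 (adjusted p = 0.257) and without the filter (adjusted p = 0.0713). Photosynthesis was lower by -0.22 (adjusted p = 0.0261; adjusted p = 0.535 with an estimated correlation), and by -0.06 without mock replicate 1 (adjusted p = 0.469). It was also lost without DOF6ioex estradiol replicate 2 or 3 (adjusted p = 0.11 and 0.111). Gibberellin metabolism was lower by -0.04, with 4 of 7 fitted lower and 3 higher (adjusted p = 0.0337, and 0.535 with an estimated correlation). It was lost without mock replicate 1 or 2 or DOF6ioex estradiol replicate 2 (adjusted p = 0.103, 0.107 and 0.149). Its median was -0.01 without DOF6ioex estradiol replicate 1 and -0.12 without replicate 3 of that group, with the call past the threshold. With median-of-ratios scaling both photosynthesis and gibberellin metabolism had an adjusted p of 0.0728, and with upper quartile scaling 0.0747. In the gibberellin metabolism list, GA20OX3 held 20.1 ± 7.98 FPKM in mock and 8.08 ± 1.56 in estradiol, the 1 member that passed adjusted over the list alone. The list of design genes, DOF6 and RGL2 as measured, passed upward (adjusted p = 0.0395; adjusted p = 0.535 with an estimated correlation) through DOF6, and not without mock replicate 1 or 3 or DOF6ioex estradiol replicate 3 (adjusted p = 0.0543, 0.423 and 0.101).

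The other lists did not pass, with adjusted p from 0.142 to 0.921. They were ABA synthesis, ABA catabolism, ABA signalling, ABA-responsive genes, dormancy regulators, maturation regulators, LEA proteins, reserve lipid mobilisation, ethylene, jasmonate, auxin, cell cycle, the DOF family, the GATA family, the testa flavonoid pathway, seed coat mucilage cells and endosperm markers. CYP707A2, an ABA 8'-hydroxylase gene, held 29.0 ± 0.388 FPKM in mock and 37.7 ± 0.342 in estradiol, with an adjusted p of 0.311 over all genes. The ABA receptor gene PYL2 had a log2 difference of -0.69 ± 0.17 (adjusted p = 0.272).

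The number of changed genes rested on the libraries, on the scaling and on the filter on low values, without which 4 genes changed. Leaving out mock replicate 1, 2 or 3 gave 8, 6 or 14 genes, DOF6ioex estradiol replicate 1, 2 or 3 gave 9, 6 or 5, and the libraries labelled rgl2-13 DOF6ioex replicate 1, 2 or 3 gave 90, 54 or 19, against 56 with median-of-ratios scaling and 105 in a fit on the 6 libraries compared.

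The comparison of the libraries labelled rgl2-13 DOF6ioex with DOF6ioex, both in estradiol, asks what the loss of RGL2 changes in seeds with DOF6 induced. As RGL2 was higher in the libraries with the mutant label, each direction here is that of the label. Of 13 cell wall loosening genes 5 rose in these libraries, and the call of the list as a group was lost with an estimated correlation (adjusted p = 0.0778 with an estimated correlation). The expansin gene EXPA2 rose from 2.93 ± 1.02 to 10.6 ± 1.64 FPKM (log2 1.58 ± 0.17, adjusted p = 0.00277), EXPA1 from 6.30 ± 1.05 to 17.2 ± 5.60 FPKM, and EXPA8 by log2 1.36 ± 0.23 (adjusted p = 0.0461). MAN7, for an endo-beta-mannanase, rose from 3.67 ± 0.696 to 8.74 ± 1.75 FPKM (n = 3 for each mean ± SD). Transcripts of storage and oil body proteins and of LEA proteins lay lower as groups with 0 members past the threshold in limma over all genes, and these group calls were lost with an estimated correlation (adjusted p = 0.0953 and 0.0619 with an estimated correlation).

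In limma 22 genes changed, 19 up and 3 down, 14 of them at least 2-fold on the log2(FPKM + 1) scale. The groups did not overlap for any of the 22, which the call nearly fixes, against 20.7% of all genes and 10% by chance. The 3 with the largest changes were AT3G01345, annotated as an expressed protein, ILA and AT1G64795. AT3G01345 fell from 104 ± 8.98 to 4.97 ± 0.219 FPKM (log2 -4.13 ± 0.10, adjusted p = 3.53e-10), and mock seeds held 103 ± 9.39. ILA, for a HEAT repeat protein, rose from 21.7 ± 0.909 to 299 ± 40.4 FPKM (log2 3.72 ± 0.15, adjusted p = 1.16e-07), with 19.9 ± 4.97 in mock. AT1G64795 rose by log2 4.19 ± 0.23 to 113 ± 5.45 FPKM; in TAIR10.1 it lies inside ILA, and how reads were assigned between the pair was not examined, so the values may not be independent.

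RGL2 itself rose by log2 0.97 ± 0.14 (adjusted p = 0.0184), a call lost in 8 of 18 other settings. The adjusted p of RGL2 was 0.0918 and 0.137 without DOF6ioex estradiol replicate 1 or 2, 0.086 without replicate 3 of the libraries labelled rgl2-13 DOF6ioex, 0.115 with the replicate number as a block, 0.0511 in a fit on the 6 libraries compared and 0.184 without the filter. AT5G11420, which is uncharacterised, rose by log2 1.25 ± 0.14 and the transcript BGI_novel_G000101, named by the authors' pipeline, by 1.02 ± 0.15. AT4G01610, for a cysteine proteinase, rose by log2 0.70 ± 0.10, and CYP81D11, a cytochrome P450 gene on the xenobiotic response list, by 0.59 ± 0.10. AT3G44006 fell from 9.15 ± 0.676 to 3.21 ± 0.258 FPKM (log2 -1.27 ± 0.11, adjusted p = 0.000336).

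Of 13 cell wall loosening genes 12 were fitted higher, 5 rose over all genes tested and 7 adjusted over the list alone (camera adjusted p = 1.51e-07; adjusted p = 0.0778 with an estimated correlation). XTH19, for a xyloglucan endotransglucosylase, rose from 0.603 ± 0.0757 to 2.26 ± 0.790 FPKM. All 16 seed storage and oil body genes were fitted lower, 0 past the threshold over all genes in limma, 8 adjusted over the list alone (camera adjusted p = 2.94e-18; adjusted p = 0.0953 with an estimated correlation). CRU2, for a cruciferin, held 3408 ± 141 FPKM in DOF6ioex estradiol and 2407 ± 89.4 in the libraries labelled rgl2-13 DOF6ioex. Of 11 LEA genes 10 were fitted lower, 0 past the threshold in limma over all genes and 5 adjusted over the list alone (camera adjusted p = 1.64e-10; adjusted p = 0.0619 with an estimated correlation). M10 held 4005 ± 103 FPKM in DOF6ioex estradiol and 3015 ± 222 in the libraries labelled rgl2-13 DOF6ioex. All tested genes together had a median log2 change of 0.11 here, which median-of-ratios scaling moved to 0.01; relative to it, the medians of the 3 lists were 0.47, -0.38 and -0.35. Without replicate 1 of the libraries labelled rgl2-13 DOF6ioex they were 0.37, -0.30 and -0.22. Without the filter on low values the cell wall and LEA medians were 0.27 and -0.29 relative to all genes, with both calls past the threshold.

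ABA-responsive genes passed downward (7 of 13 fitted lower, median -0.12 relative to all genes; adjusted p = 0.0248), and this call was lost under both scalings and with an estimated correlation (adjusted p = 0.412 with an estimated correlation). It was also lost without DOF6ioex estradiol replicate 2 or 3 (adjusted p = 0.0579 and 0.106) and without replicate 1 or 3 of the libraries labelled rgl2-13 DOF6ioex (adjusted p = 0.507 and 0.0511), and without the filter, where the median of the list turned from log2 -0.02 to 0.02 (adjusted p = 0.355). Their members went both ways, with log2 differences of 0.71 ± 0.16 for COR47 and -0.29 ± 0.10 for RD26, neither past the threshold over all genes. Adjusted over the list alone 1 member passed, COR47, against the direction of the call. The other lists, among them dormancy regulators, gibberellin metabolism, gibberellin signalling, xenobiotic response, heat shock, photosynthesis and cytosolic ribosomal proteins, did not pass (adjusted p from 0.101 to 0.989). Of the gibberellin signalling list, RGL2 was the 1 member that changed.

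**Figure D3:**
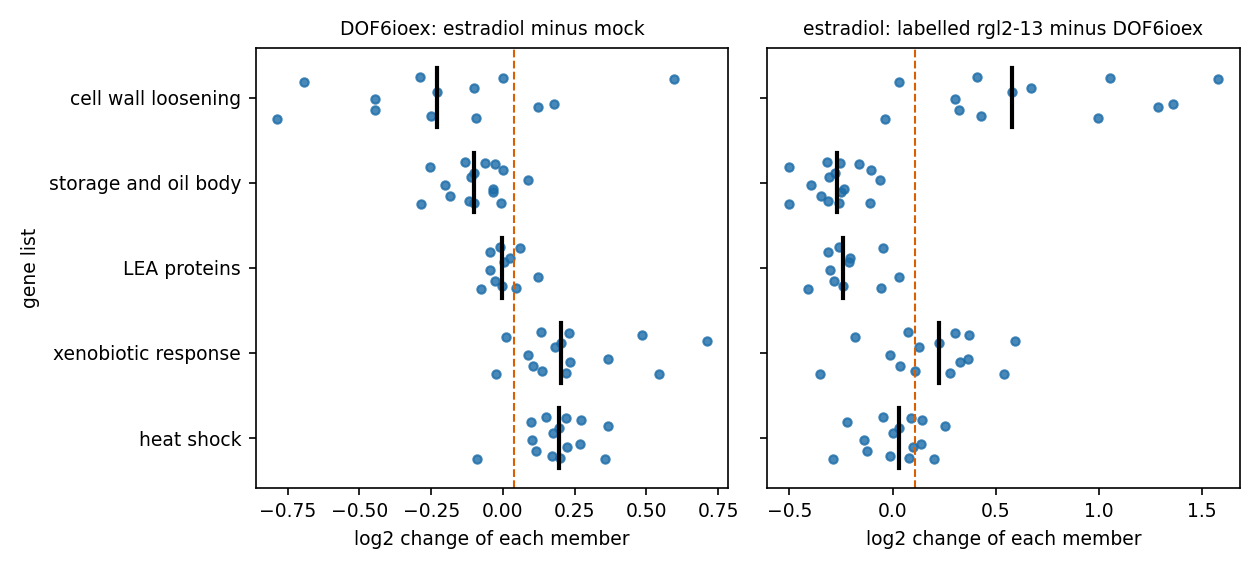
log2 change of each measured member of 5 fixed gene lists (points), the list median (black bar) and the median of all tested genes (dashed line), for estradiol minus mock in DOF6ioex and for the libraries labelled rgl2-13 DOF6ioex minus DOF6ioex in estradiol. In the second panel 12 of 13 cell wall loosening genes lie above 0, and all 16 storage and oil body genes and 10 of 11 LEA genes lie below it.

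With median-of-ratios scaling 25 genes changed, 76.0% of them up, against 86.4% without scaling. A fit on the 6 libraries compared gave 7 genes, and a fit without the filter on low values gave 4. Leaving out mock replicate 1, 2 or 3 gave 23, 11 or 12 genes, DOF6ioex estradiol replicate 1, 2 or 3 gave 13, 8 or 13, and the libraries labelled rgl2-13 DOF6ioex replicate 1, 2 or 3 gave 20, 26 or 13.

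Whether genes changed by estradiol changed back in the libraries labelled rgl2-13 DOF6ioex was asked by the overlap of these comparisons. FTM1, NRT2.6 and AT4G33560 fell with estradiol in DOF6ioex and rose in the libraries labelled rgl2-13 DOF6ioex; AT4G33560 lies below the level set for naming and is given after its values were seen. FTM1 stood at 5.50 ± 0.669 FPKM in mock, 1.22 ± 0.352 in DOF6ioex estradiol and 3.63 ± 0.0651 in the libraries labelled rgl2-13 DOF6ioex, and NRT2.6 at 5.54 ± 0.641, 2.24 ± 0.231 and 5.19 ± 1.08 FPKM. Unchanged groups sharing the DOF6ioex estradiol libraries gave 0 such genes in each of 100 simulated draws, and independent lists of these sizes would share 0.024. As hardly any gene is called where none changed, the simulated 0 does not show that 3 exceeds what shared libraries give to changed genes. Across genes, which are not independent replicates, the fold changes of the comparisons correlated at -0.325, against a mean of -0.470 (-0.936 to 0.824) in the simulation. Their covariance was -0.00977 against -0.00787 (-0.0263 to 0.00544), so both lay inside the range of unchanged groups. The 3 shared libraries could not be split into parts of 2, so part of the overlap may come from them. Leaving out single libraries gave 1 to 5 such genes: 1 without mock replicate 2 or 3 or DOF6ioex estradiol replicate 2 or 3, and 5 without replicate 1 or 2 of the libraries labelled rgl2-13 DOF6ioex.

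The libraries labelled rgl2-13 DOF6ioex in estradiol differ from DOF6ioex mock in both genotype and treatment, so this comparison describes where they lie and separates neither. All 21 genes changed by estradiol in DOF6ioex had the same fitted direction here, and 4 rises and 6 falls passed again, with DOF6, DIN2, LSU3 and BGLU28 among the rises. Both comparisons use the same mock libraries, and in simulated unchanged groups the median was also 21 of the 21 genes with the smallest p (0 to 21). The shared direction alone therefore cannot show whether an effect is shared. In limma 78 genes changed, 62 up and 16 down (79.5% up). A fit on the 6 libraries compared gave 18 genes, and a fit without the filter on low values gave 8. With median-of-ratios scaling 138 genes changed, 65 up and 73 down (47.1% up), and the median of all genes was log2 0.00 in place of 0.14. AOX1A, the mitochondrial alternative oxidase gene, and APR3, for an adenylylsulfate reductase, both singled out after their values were seen, rose by log2 1.32 ± 0.19 and 1.03 ± 0.18. CYP707A2 rose by log2 0.54 ± 0.09 (adjusted p = 0.0283).

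The 10 genes called in the same direction in both comparisons with mock stand against 0.038 for independent lists and a median of 0 in 100 simulated draws that share the mock libraries, of which 1 gave such genes, 581 of them (mean 5.81). Across genes, which are not independent replicates, the fold changes correlated at 0.519 against 0.487 (-0.719 to 0.964) in the simulation, with a covariance of 0.0173 against 0.00835 (-0.0102 to 0.0404). Both observed values lay inside the simulated range, and part of the overlap may come from the 3 shared mock libraries. Leaving out mock replicate 1, 2 or 3 gave 23, 7 or 36 changed genes, DOF6ioex estradiol replicate 1, 2 or 3 gave 59, 33 or 56, and the libraries labelled rgl2-13 DOF6ioex replicate 1, 2 or 3 gave 128, 224 or 29. Storage and oil body genes (16 of 16 fitted lower, camera adjusted p = 5.64e-26; adjusted p = 0.0636 with an estimated correlation) and LEA genes (10 of 11; adjusted p = 3.86e-11; adjusted p = 0.0532 with an estimated correlation) were lower than in mock too. ABA-responsive genes (9 of 13; adjusted p = 0.000106; adjusted p = 0.122 with an estimated correlation; the 1 called member, COR47, rose by log2 0.87) and gibberellin metabolism (5 of 7; adjusted p = 0.0323; adjusted p = 0.422 with an estimated correlation) also passed downward. Passing upward were cell wall loosening (11 of 13; adjusted p = 0.0138; adjusted p = 0.344 with an estimated correlation), xenobiotic response (12 of 15; adjusted p = 0.00339; adjusted p = 0.422 with an estimated correlation) and the design genes (adjusted p = 0.000111; adjusted p = 0.0952 with an estimated correlation). The other lists did not pass (adjusted p from 0.0867 to 0.851).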

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

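Library weights were the 1 setting here added after the data had been seen. With a pseudocount of 0.1 the counts were 19, 24 and 76 genes for estradiol against mock, for the libraries labelled rgl2-13 DOF6ioex against DOF6ioex in estradiol and for the former against mock, close to the 21, 22 and 78 reported; 4 genes changed in opposite directions in the first pair in place of 3. No gene called and named for the first 2 comparisons changed sign. The list tests were rerun for these 2 comparisons only, and not for the fit on 6 libraries or the stricter thresholds. Their camera direction held, but the median moved from log2 -0.10 to 0.01 for storage genes without mock replicate 1, from -0.11 to 0.02 for gibberellin signalling without DOF6ioex estradiol replicate 2, and from -0.02 to 0.01 for ABA-responsive genes without replicate 3 of the libraries labelled rgl2-13 DOF6ioex (0.02 without the filter).

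In the same order of comparisons, no filter on low values gave 4, 4 and 8 genes, with 0 in opposite directions, from 22385 genes tested (unadjusted p under 0.05 in limma for 1397, 2633 and 4015). Median-of-ratios scaling gave 56, 25 and 138, and upper quartile scaling 57, 26 and 139; both kept the 21 genes of the first comparison. A fit on the 6 libraries compared gave 105, 7 and 18. A threshold of 2-fold on the log2(FPKM + 1) scale gave 14, 14 and 16, with 1 in opposite directions. Limma treat against 1.5-fold gave 2, 3 and 5, with 0. Weights estimated gene by gene gave 231, 877 and 2599, with 49. The default estimate of the weights, tried first, did not converge: replicate 3 of the libraries labelled rgl2-13 DOF6ioex weighed 0.0133 there and 4.40 in the other, so with 3 libraries per group nothing is rested on either. For the filter more genes tested is part of the change, and for the stricter thresholds it is their construction; otherwise the cause was not tested.

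With the replicate number as a block, 12, 11 and 12 genes passed, with 1 in opposite directions. Same-numbered libraries correlated between -0.41 and 0.25 in their deviations from the group means, and not every library matched its own number best, so the numbers give no sign of pairing.

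Leaving out each library in turn gave 5 to 90, 8 to 26 and 7 to 224 genes, with 1 to 5 in opposite directions. The highest count of each comparison came without replicate 1 or 2 of the libraries labelled rgl2-13 DOF6ioex. Among lists, xenobiotic response, heat shock and cell wall loosening (estradiol against mock) and storage, LEA and cell wall loosening (genotype label) were lost with the estimated correlation alone. RGL2 passed in 10 of 18 settings (adjusted p 0.000156 to 1, log2 0.85 to 1.09). Its smallest adjusted p and largest change came from the library weights, on which nothing is rested. Leaving out a mock library, which this comparison does not contain, left the change at 0.97, and these settings are among the 10. EXPA8 missed the threshold with median-of-ratios scaling. The planned count-based test and the filter on counts were not run, as the files hold FPKM, and limma treat stood in for the planned test against a fold change.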

Other observations

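The tests weighed in this part, the 2 gene lists written from memory and the GO terms were chosen only after the results had been seen. Scaling and leaving out single libraries had been planned as alternatives, but weighing explanations with them had not.

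Of the 17 genes that fell with estradiol in DOF6ioex, 10 belong to a list of 46 core low-oxygen genes of Arabidopsis, written from memory after the changed genes had been seen. Of its 39 measured members 36 were fitted lower (median log2 -0.66; camera adjusted p = 3.55e-61 over the lists added afterwards; adjusted p = 0.0164 with an estimated correlation). As the list was chosen from these data, these p are not tests of a question asked beforehand. The 29 members that had not passed alone were still lower, 26 of them by fitted sign (camera adjusted p = 8.22e-35; adjusted p = 0.0284 with an estimated correlation). LBD41 and CML38 had log2 changes of -0.82 and -1.10 without passing alone, ADH1 had -0.39, and HRE1 and HRE2, which are regulators of the response, had 0.37 and -0.26. In the libraries labelled rgl2-13 DOF6ioex 34 of the 39 were fitted lower than in mock (median log2 -0.35; camera adjusted p = 1.68e-36), a call lost with the other setting (adjusted p = 0.0573 with an estimated correlation). Against DOF6ioex estradiol the list went the other way in the libraries labelled rgl2-13 DOF6ioex: 33 of the 39 were fitted higher and 2 rose (median log2 0.33; camera adjusted p = 0.00118; adjusted p = 0.951 with an estimated correlation). All tested genes had a median log2 of 0.11 there. The list was written after falls in these same DOF6ioex estradiol libraries had been seen, so a rise against them is partly built in. The 2 that rose, FTM1 and AT4G33560, are among the genes that fell. The mean of the list in replicate 1 of that label, 4.84, lay near the mock libraries (4.90 to 5.01), with 4.38 and 4.49 in replicates 2 and 3. The GO term for response to hypoxia in the deposited annotation, with 25 measured genes, did not shift (camera adjusted p = 0.334). Of the 6 measured genes of cellular response to hypoxia 3 were fitted lower and 3 higher.

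A list of 16 sulfur-limitation genes, also written from memory afterwards, was higher with estradiol in all 11 measured members (median log2 0.66; camera adjusted p = 8.62e-16; adjusted p = 0.0496 with an estimated correlation). LSU3 and BGLU28 rose, and SDI1, APR3, APR1 and LSU2 had log2 changes of 1.17, 0.87, 0.79 and 0.63 without passing alone. The 11 were also fitted higher in the libraries labelled rgl2-13 DOF6ioex than in mock (median log2 0.77; camera adjusted p = 1.56e-09; adjusted p = 0.131 with an estimated correlation), and 5 of them rose there, among them SULTR1;2 and APR1. Among 530 GO terms, translation had the smallest camera p for estradiol against mock, and was lower with estradiol (adjusted p = 2.93e-07). Sulfate assimilation, named here because it matches the sulfur list, was higher with estradiol (adjusted p = 0.0142). In the libraries labelled rgl2-13 DOF6ioex, lipid storage was lower (adjusted p = 0.000497) and translation higher (adjusted p = 0.00396) than in DOF6ioex estradiol. With an estimated correlation 0 GO terms passed in any comparison, where 12, 8 and 19 had passed with the preset one.

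The authors' own lists of genes past a pairwise threshold hold 228 genes for estradiol against mock, 180 of them for 1 pair of libraries and 24 in both directions in different pairs. In 62.6% of the entries 1 of the values was the lowest listed, 0.01. Listed for all 3 pairs were DOF6, BGLU28, AT2G41231, AT5G42200 and BGI_novel_G000073, of which the first 4 passed here and the last was below the filter and not tested. For the genotype label the lists hold 248 genes, and ILA, AT1G64795 and AT3G01345 appear in all 3 pairs. These genes were picked out by the authors' lists, not by the naming rule.

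RGL2 was higher by log2 0.97 in the libraries that carry the rgl2-13 label. An exchange of labels between the estradiol groups is argued against by the mock libraries, which lay nearer to DOF6ioex estradiol at 17 of the 22 genes changed between these groups, AT3G01345, ILA and AT1G64795 among them. A difference in scale as the whole cause is argued against by a change of 0.85 after median-of-ratios scaling (SE 0.14, adjusted p = 0.042). An allele that still yields a counted transcript may give the same value of 0.97 and stays open, since a gene-level FPKM does not show which part of the gene was read.

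Cell wall loosening genes were fitted higher, and storage and LEA genes lower, in the libraries labelled rgl2-13 DOF6ioex than in DOF6ioex estradiol. In camera these lists passed with the preset correlation alone, and the calls were lost with an estimated one (adjusted p = 0.0778, 0.0953 and 0.0619 with an estimated correlation). The fry test, which does not set a list against other genes, gave unadjusted p of 0.000113, 0.00817 and 0.0019. Replicate 1 of that label, which stands apart from the other libraries, is not the whole source: without it the cell wall list still stood 0.37 above all genes and the LEA list -0.22 from them, and the 3 lists passed at the preset correlation. Median-of-ratios scaling divides each library by a single factor, which moves nearly all its genes alike. The lists could therefore hardly shift relative to all genes. Their passing again at the preset correlation, with a storage median of -0.39, does not test scaling as a cause. Seed lots that differ in maturity or in the rate of imbibition could give the same pattern and cannot be told apart from the genotype label, as there are 0 libraries of rgl2-13 DOF6ioex seeds without estradiol. An effect of the genotype stays open beside them.

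For estradiol against mock, leaving out each of the 6 libraries left the median of the low-oxygen list at -0.62 or further below all genes. The list means of the estradiol and mock libraries did not overlap. But the list was written after the changed genes had been seen, and 10 of its 39 measured members are such genes. Both results are thus partly built in by the choice of the list. Median-of-ratios scaling left the median of the list at -0.70. As such scaling moves nearly all genes of a library alike, it could hardly change the list relative to them. Estradiol itself, or handling of the mock seeds that gave them less oxygen, could act in place of DOF6, and the design cannot tell these apart, as no line without the construct was treated. The value of -0.49 from all genes in the libraries labelled rgl2-13 DOF6ioex against mock decides nothing, as it shares both the treatment and the 3 mock libraries. Against DOF6ioex estradiol the list stood 0.22 above all genes, a shift not past the camera threshold with the other setting (adjusted p = 0.951 with an estimated correlation). That rise decides nothing either, as the list was written after the falls in those DOF6ioex estradiol libraries had been seen. An effect of induced DOF6 on these genes is a hypothesis that stays open beside them.

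In fits on the 6 libraries compared, estradiol against mock gave 105 genes and the highest of the other splits 3. For the genotype label the values were 7 and 0, and for the libraries labelled rgl2-13 DOF6ioex against mock 18 and 1. In each comparison 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.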
